A study of Homo sapiens with 4 samples.

How the data were processed

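RNA sequencing was analysed in 4 libraries of SH-SY5Y, a human neuroblastoma cell line. Per the labels, 2 libraries came from cells carrying a lentivirus that over-expressed HDAC1 and 2 from cells carrying a control lentivirus. RNA was extracted with Trizol, per the labels' protocols, and an exposure of 48 hours is mentioned there without being named. The deposited values were read counts per gene that the authors had not normalised. Trimmomatic, Bowtie2, featureCounts and the build hg38 were named in the submitters' processing notes, without versions. Bowtie2 does not split reads over introns, so reads that span exon junctions can be lost or placed on processed pseudogenes. The annotation release, the strand setting and the treatment of reads with several matches were not given in the sources used here.

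Each table listed 60651 genes under versioned Ensembl identifiers, of which 60481 were given a symbol from a table of gene names and 58405 were found in GENCODE 29, which uses the same build (GRCh38). Gene types and coordinates were taken from GENCODE 29, which need not be the release the authors used. No count was present in any library for 24597 genes. All 37 genes of the mitochondrial chromosome were at 0 in all 4 libraries, while their nuclear copies held 7.53% and 7.14% of the counts in the over-expression libraries and 5.99% and 5.78% in the control libraries. Pseudogenes held 28.6% and 27.6% of the counts in the over-expression libraries and 27.0% and 26.9% in the control libraries, and 15 of the 20 most abundant genes were pseudogenes. Counts of genes with close copies, such as those for ribosomal proteins, actins, tubulins and HDAC1, are therefore uncertain, as are counts of overlapping and antisense genes. The Y copies of the pseudoautosomal genes, 44 in number, were kept apart and held 111992 counts over the 4 libraries.

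Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 23087 genes. Libraries were scaled by TMM, and the 2 groups were compared with edgeR's quasi-likelihood test with robust estimation, two-sided, without a replicate term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was called a change. Log2 fold changes are over-expression minus control. Their standard errors (SE) were obtained as the absolute log2 fold change divided by the square root of the test's F value. Normalised CPM values used the TMM-scaled library sizes and are given as mean ± SD over the 2 libraries of a group. The common biological coefficient of variation was 0.0662, with 2 residual degrees of freedom per gene and 61.1 prior degrees of freedom.

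Gene lists were fixed before the data were examined, 46 in all with 1356 entries, of which 1354 were matched to a gene. Lists with at least 3 tested members were compared with the other genes by camera with a preset correlation of 0.01 between genes, adjusted over 44 lists. The same test was run with an estimated correlation, which has only 2 residual degrees of freedom to estimate it from. A call lost in that run therefore does not by itself count against a list. For lists whose estimate was well above 0.01, the p-value with the preset correlation may be too small. Fry was run as well, which tests whether a list's genes move one way on balance and does not compare them with other genes. Members of a list were counted after adjustment over all genes and adjusted over the list alone.

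The genes named were set by a rule fixed before the data were examined. The rule took HDAC1, the 12 genes per direction with the largest change among those with an adjusted p under 0.05, a mean log2 CPM of at least 2, a symbol that is not a clone-based name, a LOC or LINC number or a pseudogene, and both over-expression libraries on the same side of both control libraries, the 3 most abundant such genes per direction, up to 4 members with the smallest p of each list described, and all tested class I, II and IV histone deacetylases. The 18 lists described in detail were chosen after the list results were seen, and so were all other genes named, among them members that moved against their list, the HDAC1 pseudogenes and the fibroblast genes. Some genes that the rule takes are not reported here.

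Alternatives set before the data were examined were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, estimation that was not robust, a replicate block, each library left out in turn, counts thinned to the smallest total, a test against a 1.2-fold interval, and the removal of mitochondrial, ribosomal RNA and the 20 most abundant genes. Alternatives added after seeing the data were protein-coding genes only, offsets for GC content and transcript length, and the addition of processed pseudogene counts to the parent gene.

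The tests were tried on simulated counts for the 23087 genes, drawn from the means, dispersions and library sizes of these libraries. The quasi-likelihood test recovered 80.6% of genes changed 1.5-fold, 97.0% of genes changed 2-fold and 100% of genes changed 4-fold, with 13 calls among 22844 unchanged genes. Those changed genes were taken from genes with a mean log2 CPM of at least 1, so the rates do not cover genes of fewer counts. Far fewer genes were changed than were called in the data. Camera called the list of G2/M genes that had been lowered 1.5-fold. It also called 4 other lists, each holding 1 or 2 of the changed genes, and no list without a changed gene, so that a call of this test can rest on 1 or 2 members. Genes were drawn independently of each other, so false list calls from correlated genes could not be seen.

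The libraries held 35201872 and 29949680 counts (over-expression) and 39337657 and 40475995 counts (control). Over genes with at least 20 counts in a pair, the counts of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 6.16 between the over-expression libraries and 4.82 between the control libraries. No library was therefore counted as a repeat of another. Nothing in the labels says that replicates were separate cultures or separate transductions, so p-values measure only the spread between these libraries, which may be technical. No batch is given in the labels, and a difference between the transduced lines or in their handling cannot be told apart from the effect of HDAC1.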

Results

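Transcript levels were compared between SH-SY5Y cells that over-expressed HDAC1, a class I histone deacetylase that acts in co-repressor complexes, and SH-SY5Y cells that carried a control lentivirus. SH-SY5Y is a neuroblastoma line with neuron-like, noradrenergic features. There were 2 libraries per group, with 35201872 and 29949680 counts for over-expression and 39337657 and 40475995 for control. Across tested genes, log2 CPM values correlated at r = 0.986 between the over-expression libraries, r = 0.990 between the control libraries, and r = 0.957 to 0.958 between groups, where genes are not independent replicates.

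HDAC1 transcripts were 4.77-fold higher in the over-expression libraries (log2 fold change 2.26 ± 0.07 SE, adjusted p = 1.81e-38). Its level was 190.2 ± 4.61 CPM with over-expression and 39.8 ± 0.426 CPM in control (SD, n = 2 each), from 6328 and 5645 counts against 1607 and 1672. The gene (ENSG00000116478.12) lies on chromosome 1 at 32292086 to 32333635 on the plus strand (GRCh38). Its processed pseudogenes HDAC1P2 on chromosome 1 and HDAC1P1 on chromosome 10, examined after their values were seen, rose by more, 16.02-fold (225.7 ± 16.6 against 14.1 ± 0.158 CPM, adjusted p = 2.96e-49) and 19.3-fold (42.8 ± 3.81 against 2.21 ± 0.0727 CPM, adjusted p = 4.6e-38). Reads of HDAC1 and of these copies cannot be fully separated by counting. With processed pseudogenes added to their parents, an alternative chosen after seeing the data, the log2 fold change of HDAC1 was 3.03.

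**Figure D1:**
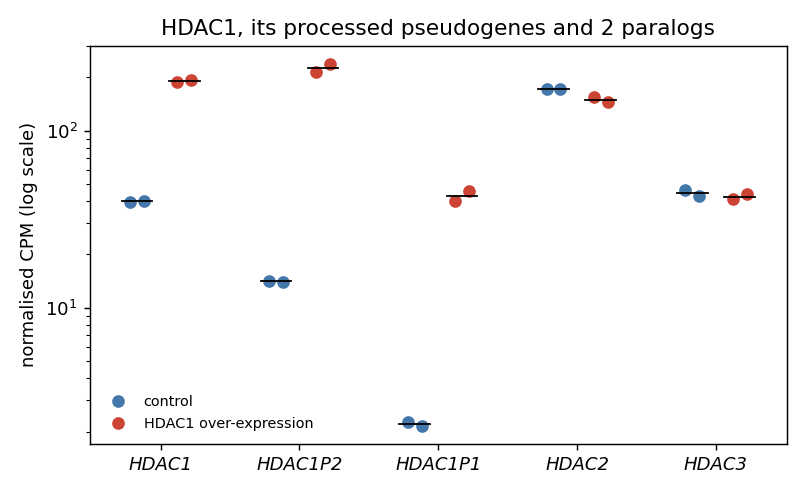
Normalised CPM on a log axis for HDAC1, its processed pseudogenes HDAC1P2 and HDAC1P1, and the paralogs HDAC2 and HDAC3, with a point per library and a line at the mean of the 2 libraries of each group. HDAC1 rose from 39.8 to 190.2 CPM and HDAC1P2 from 14.1 to 225.7 CPM, while HDAC3 was at 44.6 CPM in control and 42.4 CPM with over-expression.

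Among the other class I, II and IV deacetylases, changes were small. HDAC7 (log2 fold change 0.47 ± 0.07 SE, adjusted p = 7.7e-08) and HDAC5 (0.43 ± 0.08 SE, adjusted p = 2.86e-06) rose, both class II enzymes. HDAC10 (-0.70 ± 0.22 SE, adjusted p = 0.00785), HDAC8 (-0.28 ± 0.11 SE, adjusted p = 0.0349) and HDAC2 (-0.20 ± 0.06 SE, adjusted p = 0.00792), the closest paralog of HDAC1, fell. HDAC3 (-0.07), HDAC4 (0.10), HDAC6 (0.10), HDAC9 (0.05, or -0.04 with total counts only) and HDAC11 (-0.11) did not pass. Adjusted over the list alone, 3 members were higher and 3 lower, as over all genes, and the list as a whole was not called (camera adjusted p = 0.0866). Each of the falls did not pass in some of the runs with 1 library left out. HDAC2 was at -0.14 without over-expression replicate 2, -0.20 without control replicate 1 and -0.21 without control replicate 2. HDAC8 was at -0.13 without over-expression replicate 1 and -0.22 without control replicate 2, and HDAC10 at -0.41 without over-expression replicate 2 and -0.67 without control replicate 2. HDAC8 (-0.27) and HDAC10 (-0.70) did not pass with DESeq2 either, nor HDAC8 with thinned counts (-0.25). With offsets for GC content and length, an alternative chosen after seeing the data, HDAC2 (-0.09) and HDAC8 (-0.21) did not pass.

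Of 23087 genes tested, 10062 (43.6%) changed at an adjusted p under 0.05, 5158 higher and 4904 lower with over-expression. Protein-coding genes made up 3994 of the higher and 3723 of the lower genes. Most changes were small. At least 2-fold differences were seen for 2669 genes (1500 higher, 1169 lower), at least 4-fold for 613 higher and 252 lower genes, and at least 8-fold for 231 higher and 82 lower genes. The groups did not overlap for 70.2% of tested genes, where chance gives 33.3% for 2 libraries against 2. With total counts only in place of TMM, the split was 4098 higher and 6357 lower, so the near-even split depends on the scaling. Restricted to protein-coding genes, an alternative chosen after seeing the data, 1741 genes changed at least 2-fold.

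Among the 12 genes the rule named for the largest rises, CXCL12 was the most abundant. CXCL12, a chemokine that guides migrating cells, rose 40.6-fold (log2 fold change 5.34 ± 0.08 SE, adjusted p = 6.52e-56), from 8.50 ± 0.506 to 345.4 ± 0.126 CPM. PLN, an inhibitor of the sarcoplasmic reticulum calcium pump, rose by 5.65 ± 0.22 SE on the log2 scale from 0.365 to 18.5 CPM, and FGF7, a fibroblast growth factor, by 5.25 ± 0.17 SE from 0.765 to 29.3 CPM. TRIM63, a ubiquitin ligase of muscle (5.19 ± 0.30 SE), LRRC17, a leucine-rich repeat protein (4.74 ± 0.14 SE), and HSD11B1, which regenerates cortisol from cortisone (4.41 ± 0.17 SE), followed. The others were PI3, an elastase inhibitor (4.34), APOL6, an apolipoprotein L (4.28), GPNMB, a transmembrane glycoprotein (4.25), CCKAR, a cholecystokinin receptor (4.24), C1S, a complement protease (4.14), and PRLR, the prolactin receptor (4.08).

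Among the 12 genes the rule named for the largest falls, JUN was the most abundant. JUN, an immediate early transcription factor, fell 4.78-fold (log2 fold change -2.26 ± 0.06 SE, adjusted p = 1.45e-40), from 490.3 ± 16.5 to 102.6 ± 1.18 CPM. ARC, a synaptic activity-regulated gene, changed by -2.21 ± 0.09 SE, POU3F2, a neural transcription factor, by -2.33 ± 0.15 SE, ONECUT2, a homeobox factor, by -2.25 ± 0.15 SE, GABRD, a GABA receptor subunit, by -2.36 ± 0.20 SE, and BMP7, a bone morphogenetic protein, by -2.10 ± 0.15 SE. EXPH5, an effector of vesicle transport, was at -2.77 ± 0.17 SE and SLC22A23, a transporter of the organic ion family, at -2.24 ± 0.21 SE. TSPEAR on chromosome 21 (44497892 to 44711580) showed the largest fall of the genes the rule named, -3.15 ± 0.12 SE (61.4 to 6.98 CPM), together with the antisense transcripts inside its span, TSPEAR-AS2 (-2.56) and TSPEAR-AS1 (-2.27). These and SLC16A4-AS1 (-2.39) are uncertain as single genes, since reads of overlapping genes cannot be assigned without strand.

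**Figure D2:**
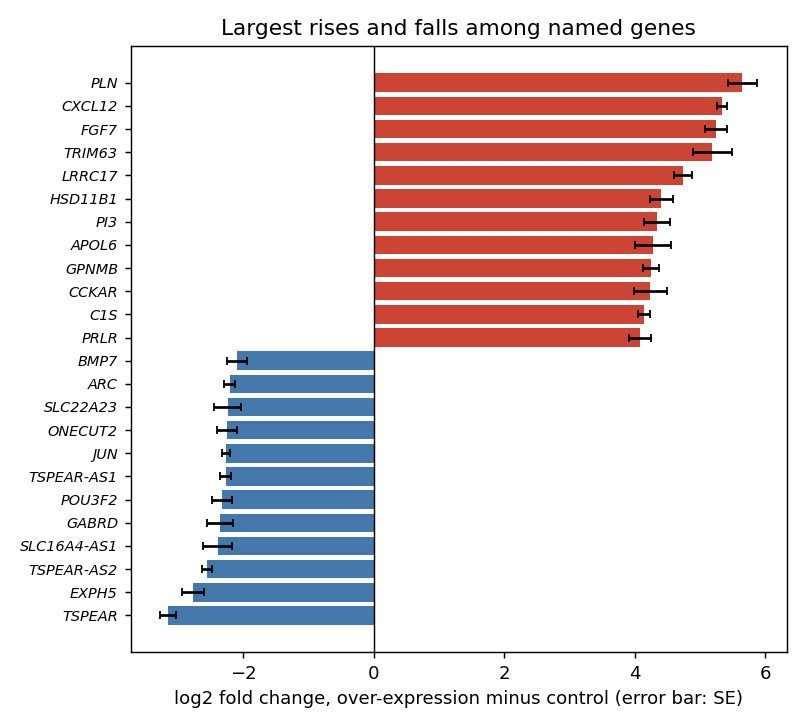
Log2 fold change, over-expression minus control, of the 12 largest rises and 12 largest falls that the rule named, with bars from 0 and error bars of 1 SE (n = 2 libraries per group). Rises ran from 4.08 for PRLR to 5.65 for PLN and falls from -2.10 for BMP7 to -3.15 for TSPEAR.

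The most abundant genes the rule named changed by less than 2-fold. ACTB (0.38 ± 0.06 SE) and ACTG1 (0.55 ± 0.06 SE), the cytoplasmic actins, rose. RGS5, a regulator of G protein signalling (-0.39 ± 0.06 SE), TUBB (-0.25 ± 0.06 SE) and TUBA1A (-0.27 ± 0.06 SE), which encode tubulins, fell. Actin and tubulin counts are uncertain because these genes have many processed copies.

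Extracellular matrix and mesenchymal genes mostly rose with over-expression. Of 48 tested genes for matrix and its remodelling, 37 were higher, 5 lower and 6 did not pass, the same counts as adjusted over the list alone, with a median log2 fold change of 0.82 (camera adjusted p = 1.68e-31, but adjusted p = 0.148 with an estimated correlation). COL3A1, a fibrillar collagen, rose 9.85-fold from 67.9 ± 0.663 to 669.2 ± 14.98 CPM (log2 fold change 3.30 ± 0.06 SE), COL5A1 by 2.41 ± 0.07 SE, SPARC, a matrix glycoprotein, by 1.96 ± 0.06 SE, and TNC, tenascin C, by 1.90 ± 0.06 SE. COL2A1, a cartilage collagen, went the other way (-3.21), as did COL9A2 (-1.34), LAMA1 (-1.14), COL11A1 (-1.02) and LOX (-0.75). In the list of mesenchymal neuroblastoma and Schwann-like genes, 18 of 25 were higher, 2 lower and 5 did not pass, again as adjusted over the list alone, with a median of 1.07 (camera adjusted p = 8.17e-22, but adjusted p = 0.148 with an estimated correlation). VIM, the intermediate filament vimentin, rose by 1.62 ± 0.06 SE and FOSL2, a transcription factor of the FOS family, by 1.52 ± 0.07 SE, whereas TWIST1 (-0.46) fell. COL3A1 and COL5A1 are in both lists. Of 27 tested genes abundant in fibroblasts, a list written after the rise of matrix genes was seen and partly shared with both lists, 23 were higher and 1 lower.

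Inflammatory and interferon-stimulated genes were mostly higher as well, in the libraries where 23 of the 27 fibroblast genes were higher (median 1.08). Among 24 NF-kB and inflammatory genes, 21 were higher, 1 was lower and 2 did not pass, as also adjusted over the list alone (median 1.46, camera adjusted p = 6.85e-22, but adjusted p = 0.171 with an estimated correlation). CCL2, a monocyte chemokine, rose by 2.05 ± 0.07 SE (69.9 ± 1.04 to 288.8 ± 16.95 CPM), NFKBIA and NFKBIZ, feedback regulators of NF-kB, by 2.21 ± 0.07 SE and 2.06 ± 0.09 SE, and ICAM1, an adhesion molecule, by 1.64 ± 0.09 SE. REL, a subunit of NF-kB, fell (-0.45), and RELA (0.10) did not pass. Of 38 interferon-stimulated and antiviral sensing genes, 33 were higher, 1 lower and 4 did not pass, with the same counts adjusted over the list alone (median 1.51, camera adjusted p = 3.49e-16, but adjusted p = 0.148 with an estimated correlation). The clearest were genes of class I antigen presentation, B2M (1.49 ± 0.06 SE, 167.9 ± 7.41 to 471.2 ± 16.7 CPM), HLA-C (1.59 ± 0.07 SE), HLA-E (1.77 ± 0.09 SE) and HLA-B (2.84 ± 0.16 SE), whose close sequences can share reads. IFI27 fell (-1.16), and IFIT1 (0.34) did not pass.

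Neuronal genes were mostly lower. In the same libraries, a list of nuclear-retained and other non-coding RNAs was lower too (median -0.61, adjusted p = 0.00519 by camera, adjusted p = 0.279 with an estimated correlation). That list was written as a sign of the RNA fraction sampled. It also holds RNAs not retained in the nucleus, such as GAS5 and RN7SL1, so its median does not read out that fraction. No link was tested between that list and the falls it is set beside here and below. Of 28 genes in the list of REST and genes it represses in non-neuronal cells, 24 were lower, 2 higher and 2 did not pass, as adjusted over the list alone (median -0.89, camera adjusted p = 3.7e-16, but adjusted p = 0.181 with an estimated correlation). VGF, a neuropeptide precursor, fell by 0.96 ± 0.06 SE on the log2 scale from 1157 ± 65.0 to 595.8 ± 25.0 CPM. CHGA and CHGB, granins of secretory granules, were at -0.94 ± 0.06 SE and -0.93 ± 0.06 SE and UNC13A, a synaptic vesicle priming gene, at -1.07 ± 0.07 SE, while REST itself (0.13) did not pass. SCN2A (0.65) and KCNH2 (0.36), ion channel genes, rose. In the list of neuronal cytoskeleton, axon and synapse genes, 29 of 40 were lower, 5 higher and 6 did not pass, as adjusted over the list alone (median -0.54, camera adjusted p = 8.93e-12, but adjusted p = 0.237 with an estimated correlation). ELAVL3, a neuronal RNA-binding protein (-1.30 ± 0.06 SE), RAB3A, a synaptic vesicle GTPase (-1.51 ± 0.09 SE), and BSN, bassoon of the presynaptic zone (-1.36 ± 0.07 SE), fell. SYT4, a synaptotagmin (0.95 ± 0.06 SE), SYN2 (1.12) and NRXN3 (1.23) rose.

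Noradrenergic genes were mostly lower, in libraries where the list of nuclear-retained and other non-coding RNAs was lower too (median -0.61). A link between these falls was not tested. Of 23 adrenergic regulators and noradrenergic genes, 15 were lower, 5 higher and 3 did not pass, or 15 lower and 6 higher adjusted over the list alone (median -0.44, camera adjusted p = 0.00014, but adjusted p = 0.215 with an estimated correlation). DBH, the enzyme that makes noradrenaline, fell 2.76-fold from 877.8 ± 26.7 to 318.2 ± 3.56 CPM (log2 fold change -1.46 ± 0.06 SE). Among the genes that rose were the transcription factors TBX2 (0.57), ISL1 (0.25) and HAND1 (0.17).

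Cell cycle genes and genes of double-strand break repair were mostly lower. The list of nuclear-retained and other non-coding RNAs was lower in the same libraries (median -0.61). No tested gene of the G1/S list was higher and 36 of 40 were lower, both over all genes and adjusted over the list alone (median -0.55, camera adjusted p = 1.11e-12, but adjusted p = 0.181 with an estimated correlation). EXO1, an exonuclease (-0.97 ± 0.07 SE), HELLS, a chromatin helicase (-1.13 ± 0.10 SE), BRIP1, a DNA helicase (-0.82 ± 0.08 SE), and MCM3 of the replicative helicase (-0.64 ± 0.06 SE) fell. Of 43 genes of the G2/M list, 39 were lower and none higher, or 40 lower adjusted over the list alone (median -0.54, camera adjusted p = 2.1e-12, but adjusted p = 0.215 with an estimated correlation). TOP2A, a topoisomerase, went from 386.1 ± 17.02 to 237.4 ± 7.72 CPM (-0.70 ± 0.06 SE), and CDK1, the mitotic kinase, from 77.9 ± 3.29 to 46.9 ± 0.736 CPM (-0.73 ± 0.07 SE). HJURP, a centromere chaperone (-0.74 ± 0.07 SE), and TACC3, a spindle protein (-0.64 ± 0.06 SE), also fell. For double-strand break repair and damage signalling, 18 of 28 were lower, 2 higher and 8 did not pass, as adjusted over the list alone (median -0.34, camera adjusted p = 0.00014, but adjusted p = 0.43 with an estimated correlation). XRCC2 (-1.12 ± 0.07 SE) and RAD54L (-1.59 ± 0.10 SE), genes of homologous recombination, fell, while NBN (0.55) and RAD50 (0.47) of the break-sensing complex rose.

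Immediate early genes were lower more often than higher. The median of the list of nuclear-retained and other non-coding RNAs was as low (-0.61). Among 27 tested, 15 were lower, 7 higher and 5 did not pass, or 17 lower and 7 higher adjusted over the list alone (median -0.61, camera adjusted p = 3.77e-08, but adjusted p = 0.252 with an estimated correlation). Besides JUN and ARC, FOSB fell by 1.90 ± 0.10 SE on the log2 scale and FOS, from 429.0 ± 17.7 to 201.6 ± 2.92 CPM, by 1.09 ± 0.06 SE. IER3 (1.07), EGR2 (0.96), JUNB (0.74) and CCN1 (0.74) rose.

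Signalling genes of the BMP and TGF-beta pathways were more often higher than lower, in libraries where 23 of 27 fibroblast genes were higher (median 1.08). Of 27 tested, 15 were higher, 4 lower and 8 did not pass, or 16 higher and 4 lower adjusted over the list alone (median 0.40, camera adjusted p = 1.41e-10, but adjusted p = 0.171 with an estimated correlation). GREM1, a secreted BMP antagonist (1.69 ± 0.07 SE), SMAD1, a BMP signal transducer (2.21 ± 0.09 SE), and TGFB1, a TGF-beta ligand (1.86 ± 0.09 SE, 17.5 ± 0.337 to 63.4 ± 2.22 CPM), rose. BMP7 (-2.10), BMPR1B (-0.51), CHRD (-0.46) and SMAD5 (-0.23) fell. Wnt genes went both ways, 13 of 28 higher, 9 lower and 6 not passing, or 13 higher and 10 lower adjusted over the list alone (median 0.14, camera adjusted p = 0.00715, but adjusted p = 0.252 with an estimated correlation, and the call was lost with no low-count filter). LGR5, an R-spondin receptor, rose by 1.77 ± 0.06 SE from 205.2 ± 3.94 to 700.5 ± 20.5 CPM, SFRP1, a secreted Wnt antagonist, by 1.98 ± 0.07 SE, and TCF7L2, a transcription factor of the pathway, by 1.87 ± 0.10 SE. DKK1, a secreted antagonist (-1.30 ± 0.07 SE), and AXIN2, a feedback target (-1.09), fell.

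Lysosomal, iron and oxidative stress genes were more often higher than lower. Fibroblast genes rose by more in the same libraries (23 of 27 higher, median 1.08). Autophagy and lysosome genes were higher in 28 of 48 cases, lower in 3, and 17 did not pass, or 29 higher and 3 lower adjusted over the list alone (median 0.35, camera adjusted p = 8.78e-07, but adjusted p = 0.43 with an estimated correlation). SQSTM1, an autophagy receptor, rose by 1.48 ± 0.06 SE (80.8 ± 4.22 to 225.7 ± 4.97 CPM), CTSB, a lysosomal protease, by 0.87 ± 0.06 SE, and NPC2, a lysosomal cholesterol carrier, by 1.25 ± 0.09 SE. Among 20 ferroptosis and iron genes, 13 were higher, 1 lower and 6 did not pass, or 14 higher and 1 lower adjusted over the list alone (median 0.43, camera adjusted p = 1.69e-06, but adjusted p = 0.181 with an estimated correlation). FTH1, the ferritin heavy chain, which has many processed copies, rose 3.06-fold from 512.6 ± 20.5 to 1570 ± 20.1 CPM. NCOA4, the receptor for ferritin degradation (1.27 ± 0.07 SE), CP, ceruloplasmin (3.51 ± 0.21 SE), and GPX4, which reduces lipid hydroperoxides (0.64 ± 0.07 SE), also rose. Of 32 oxidative stress genes and NRF2 targets, 16 were higher, 4 lower and 12 did not pass, as adjusted over the list alone (median 0.26, camera adjusted p = 0.000189, but adjusted p = 0.494 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, rose 4.97-fold from 120.6 ± 1.44 to 599.9 ± 3.18 CPM, KEAP1 by 0.84 ± 0.07 SE and NFE2L2, which encodes NRF2, by 0.78 ± 0.07 SE. ME1 (-0.65), CAT, catalase (-0.47), TXNRD1 (-0.33) and GSTP1 (-0.20) fell.

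In the list of Polycomb and DNA methylation genes, 14 of 28 were lower, 5 higher and 9 did not pass, or 16 lower and 5 higher adjusted over the list alone (median -0.31, camera adjusted p = 0.00476, but adjusted p = 0.252 with an estimated correlation). This fall is smaller than that of the list of nuclear-retained and other non-coding RNAs (median -0.61). TET1, which oxidises methylated cytosine, fell 2.72-fold (-1.44 ± 0.10 SE, 41.1 ± 1.69 to 15.1 ± 0.169 CPM), and EZH1, a histone methyltransferase (-0.73 ± 0.08 SE), and MTF2, a Polycomb cofactor (-0.64 ± 0.08 SE), fell, while RING1, a Polycomb ubiquitin ligase (0.71 ± 0.08 SE), rose. Subunits of the NuRD, SIN3, CoREST and MiDAC complexes, in which HDAC1 acts, were lower in 13 of 39 cases, higher in 7, and 19 did not pass, or 14 lower and 7 higher adjusted over the list alone. That list was not called (median -0.06, camera adjusted p = 0.184). CHD5, a neuronal NuRD helicase (-0.99 ± 0.09 SE), GATAD2B (-0.50 ± 0.07 SE), ING1 (-0.58 ± 0.09 SE) and ARID4A (-0.70 ± 0.11 SE) fell.

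**Figure D3:**
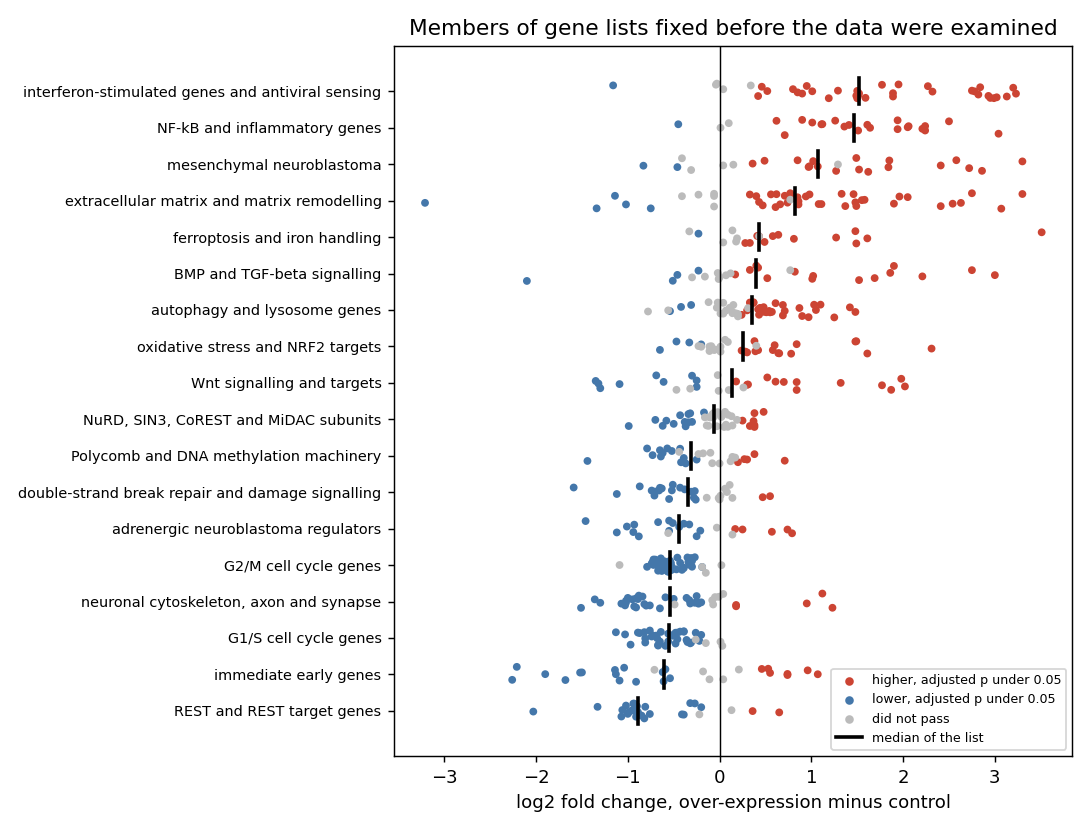
Log2 fold change, over-expression minus control, of the tested members of 18 gene lists, with a point per gene coloured by whether it was higher, lower or did not pass at an adjusted p under 0.05, a black bar at each list's median, and vertical scatter within a list for legibility. Medians ran from 1.51 for interferon-stimulated genes to -0.89 for REST and its target genes.

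Of the lists not described so far, camera called 3 more as higher, namely amyloid and tau genes (16 of 28 higher, 6 lower, adjusted p = 0.00309), apoptosis regulators (17 of 33 higher, 4 lower, or 19 higher adjusted over the list alone, adjusted p = 0.0134) and the unfolded protein response (15 of 25 higher, 0 lower, adjusted p = 0.038). It called 5 more as lower. These were heat shock genes and chaperones (12 of 23 lower, 4 higher, adjusted p = 0.00458) and nuclear-retained and other non-coding RNAs (5 of 7 lower, 1 higher, or 6 lower adjusted over the list alone, median -0.61, adjusted p = 0.00519). Hypoxia and glycolysis genes (19 of 33 lower, 5 higher, adjusted p = 0.0123), HOX genes (6 of 12 lower, 0 higher, or 7 lower adjusted over the list alone, adjusted p = 0.0393) and cytosolic ribosomal proteins (20 of 55 lower, 2 higher, or 19 lower adjusted over the list alone, adjusted p = 0.0429) followed, the last of which share reads with pseudogenes. With an estimated correlation the adjusted p was 0.268, 0.449 and 0.569 for the higher lists and 0.569, 0.279, 0.52, 0.47 and 0.73 for the lower lists, in the same order. The 3 higher lists rose in the libraries where 23 of 27 fibroblast genes were higher (median 1.08). Epithelial markers (4 of 9 higher, 1 lower, adjusted p = 0.471), p53 targets (8 of 31 higher, 14 lower, or 15 lower adjusted over the list alone, adjusted p = 0.169), nuclear-encoded oxidative phosphorylation genes (8 of 59 higher, 10 lower, or 4 higher and 6 lower adjusted over the list alone, adjusted p = 0.76) and housekeeping genes (4 of 16 higher, 3 lower, adjusted p = 0.417) were not called. Counts adjusted over the list alone were the same where none is given. For neurotransmitter receptors the median of 0.23 and the direction of the test, which was lower, differed (adjusted p = 0.56). Lists of the integrated stress response, MYC targets, Notch signalling, base excision repair, cyclin-dependent kinase inhibitors, acetyltransferases, mitochondrial quality control, neurotrophin signalling, replication-dependent histones, sirtuins, sterol synthesis and synuclein-related genes were not called either, with adjusted p from 0.0585 to 0.995. No haematopoietic or mitochondrially encoded list could be tested, with 2 and 0 tested members. In total 25 of 44 lists were called, 12 higher and 13 lower. With an estimated correlation 0 were called, while 10 had an unadjusted p under 0.05. Fry, which tests each list against no change and not against the other genes, called 32.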

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

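The restriction to protein-coding genes, the GC content and length offsets and the addition of processed pseudogenes to their parents were chosen after seeing the data, and the other alternatives before. Of 1902 values of 106 named genes under alternatives, 1888 kept their direction and their side of the threshold, 12 no longer passed, 1 newly passed and 1 reversed. Apart from the deacetylases, these genes were picked for large changes, abundance or small p in the same fit. Their staying past the threshold was therefore likely from the start, and the count does not measure how robust other genes are. The reversal was HDAC9, which did not pass in either case, at -0.04 with total counts only, where the median of all genes was at -0.10. The values that no longer passed were those of HDAC2, HDAC8 and HDAC10, with single libraries left out, DESeq2, thinning or GC content and length offsets, and the one that newly passed was HDAC9 with GC content and length offsets (0.13). HDAC1 ranged from 2.16 to 3.03 on the log2 scale, the highest with processed pseudogenes added to it. The count of genes changed at least 2-fold was 1741 with protein-coding genes only, where fewer genes were tested. The lists called fell from 25 to 0 with an estimated correlation. For the matrix and mesenchymal lists that correlation (-4.5e-04 and -0.015) was below the preset 0.01, so correlation between genes does not account for their lost calls. That run has only 2 residual degrees of freedom and can hardly call a list after adjustment. Its lost calls therefore do not by themselves count against the lists. Estimates for the other called lists ran from -0.033 for Wnt genes to 0.36 for cytosolic ribosomal proteins. Where the estimate was well above 0.01, as for heat shock genes (0.31) and oxidative stress genes (0.24), correlation between genes may account for the lost call. The p-values with the preset correlation may be too small for such lists. Of 306 values of the 18 lists by camera with the preset correlation, 305 kept their side, the exception being Wnt genes with no low-count filter. These lists were chosen after their results were seen, so that count does not speak for the other lists. By fry, which tests another hypothesis, the NuRD, SIN3, CoREST and MiDAC list passed (adjusted p = 0.0305, against 0.184 by camera). The number of lists called by camera with the preset correlation went down to 20 with protein-coding genes only, 22 without control replicate 2, 23 without over-expression replicate 2 and 23 with a CPM of at least 1 in 2 libraries, and up to 27 with GC content and length offsets. Estimation that was not robust does not enter camera and gave no list value.

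Genes changed numbered 7764 to 9493 when 1 library was left out, where the lone library is assumed to vary like the other group, and 8305 with DESeq2. Between 74.9% and 85.5% of the calls that could be tested were shared in the same direction with 1 library left out, and 82.4% with DESeq2. Against a 1.2-fold interval 6012 genes passed, 3146 higher and 2866 lower. No gene was called in the opposite direction under any alternative except 4 with processed pseudogenes added to their parents. Same-numbered libraries of the 2 groups did not deviate together (correlation of deviations -0.0042), and with the replicate block 9779 genes changed, 2619 of them at least 2-fold, HDAC1 stayed at 2.26 and 25 lists were called. At this depth genes of few counts are limited, since 24597 genes had no count and 23087 were tested.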

Other observations

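The gene groups, the locus and the tests of the HDAC1 read share and of type I collagen in this part were chosen only after the results were seen. Complement genes were a group not among the lists fixed in advance. Of 22 tested components and regulators, 12 were higher, 1 lower and 9 did not pass, with a median log2 fold change of 0.93 (camera p = 2.56e-20, p = 0.0213 with an estimated correlation). The group was picked because C1S and C1R were among the largest rises, so these p-values are not independent evidence. Of 27 tested genes abundant in fibroblasts, 23 were higher in the same libraries (median 1.08), and the complement genes do not tell other mesenchymal-like cells from a change within the SH-SY5Y cells. C1S and C1R, the proteases of the classical pathway, rose by 4.14 ± 0.09 SE and 4.02 ± 0.12 SE, C3, the central component, by 2.74 ± 0.07 SE from 29.1 ± 2.24 to 194.1 ± 13.6 CPM, and CFB, of the alternative pathway, by 3.02 ± 0.22 SE. C7 of the membrane attack complex (1.92 ± 0.07 SE) and the regulators CLU (2.07 ± 0.07 SE) and CD59 (0.83 ± 0.07 SE) also rose, whereas CFD, an alternative pathway protease, fell (-1.54 ± 0.38 SE) and SERPING1, the inhibitor of C1S and C1R, was at -0.23 ± 0.18 SE and did not pass.

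Zinc finger genes with a ZNF symbol were lower more often than higher, 185 against 72 of 492 tested, with 235 not passing (median -0.15, camera p = 0.00245, p = 0.249 with an estimated correlation). The list of nuclear-retained and other non-coding RNAs was lower by more (median -0.61, 5 of 7 lower). Among the ZNF genes ZNF208 fell by 2.33 ± 0.27 SE on the log2 scale and ZNF467 rose by 1.92 ± 0.17 SE. Protocadherins were higher in 15 and lower in 2 of 59 cases and as a group did not pass (camera p = 0.144, p = 0.556 with an estimated correlation). On chromosome 21, the fall of TSPEAR (-3.15) and its antisense transcripts was shared by the neighbouring non-coding genes LINC02575 (-2.50 ± 0.09 SE, 91.0 to 16.1 CPM) and AP001065.2 (-4.37 ± 0.23 SE). IMMTP1, a processed pseudogene within the span of TSPEAR whose counts can include reads of its parent gene, was at -0.04 ± 0.07 SE. HEPFAL beside LINC02575 was at 0.26 ± 0.47 SE with under 1 CPM in both groups (0.973 against 0.815). Neither passed, and neither tells whether the fall extends over all of the locus. On either side LRRC3 was at -0.57 ± 0.08 SE, UBE2G2 at -0.14 ± 0.06 SE, which did not pass, and SUMO3 at 0.25 ± 0.07 SE.

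The processed pseudogenes of HDAC1 rose with HDAC1 and by more. Against a fixed share of HDAC1 reads being placed on them stands the ratio of pseudogene to HDAC1 counts, 1.41 ± 0.073 with over-expression and 0.409 ± 0.010 in control (SD, n = 2), a 3.45-fold difference. Placement of reads of multi-exon mRNAs on processed pseudogenes remains open, since 169 of 190 other processed pseudogenes whose parent changed at least 1.5-fold had the parent's sign (88.9%, exact binomial 95% interval 83.6% to 93.0%, although pairs that share a parent are not independent). Together these are consistent with more of the reads of the added transcript than of the endogenous one landing on the copies, which may follow if the vector carried the coding sequence without untranslated parts. That was not tested, since the vector sequence and counts per exon were not analysed here, and the 3 genes together rose 8.17-fold (56.1 ± 0.195 to 458.7 ± 25.0 CPM) against 4.77-fold for HDAC1 alone.

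Mesenchymal and matrix genes rose more often than they fell, 18 against 2 of 25 and 37 against 5 of 48, although neither list was called with an estimated correlation (adjusted p = 0.148 for both). The adrenergic transcription factors moved apart, 5 of 10 higher and 4 lower, which a lower share of adrenergic cells alone would not give. A small loss of such cells could be hidden by other changes in these factors. It stays open, since 15 of 23 adrenergic regulators and noradrenergic genes were lower. COL1A1 and COL1A2 together gained 19.8 ± 0.588 CPM, 3.29% of the 601.3 ± 14.99 CPM that COL3A1 gained. This argues against fibroblast-like cells with at least as much type I as type III collagen, although the comparison was chosen after these values were seen. No reference profile of such cells was used. Over the 27 tested of 30 fibroblast genes the median log2 fold change was 1.08 (bootstrap 95% interval 0.97 to 1.52). That met the outcome set in advance for admixture of fibroblast-like cells, a median over 1, although the interval reached below it. This does not settle the cause, since that list was written after the rise was seen and partly shares its genes. Other mesenchymal-like cells and a change within the SH-SY5Y cells therefore cannot be told apart. The effect of HDAC1 itself and a difference between the transduced lines also remain open.

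Most called genes, 7393 of 10062, changed by less than 2-fold. GC content and length bias is argued against as the whole cause, since 95.4% of these calls were kept in the same direction with GC and length offsets (99.6% of these genes had both values). After thinning, 96.4% of those tested were kept. That does not decide on a difference in library size. The fit already scaled the libraries, and thinning to 29949680 counts left most counts of each library, so few calls could be lost. A chromosome-scale copy number difference is argued against by the medians of 40 chromosome arms. The largest distance from the median of arms was 0.102, below the 0.15 set in advance (permutation p = 0.28 over 10000 permutations of genes). It was a fall on 19q (-0.102), with 19p at -0.084 and 11p at 0.087. The permutations took the largest distance over arms of unequal size, so their p-value does not exclude a small shift of a large arm. What also stays open is an effect of HDAC1, a difference between the transduced lines and a difference in handling, which the design confounds with the groups. The number of such calls also rests on the spread between libraries that are not stated to be separate cultures.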
